A study of Mus musculus with 10 samples.

How the data were processed

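RNA abundance was measured in 10 samples of mouse colon tumour, 5 from Ucp2+/+ (WT) and 5 from Ucp2-/- (KO) animals of the C57BL6/J strain. Ucp2 encodes a carrier protein of the inner mitochondrial membrane. The tumours came from the AOM/DSS model, in which the carcinogen azoxymethane is followed by dextran sodium sulphate, a polymer that injures and inflames the colon, and they were taken at week 15 of that protocol. Per the labels' protocols, total RNA was amplified with a whole-transcript kit, labelled with biotin and hybridised to Affymetrix arrays, 1 colour and 1 array per sample. The labels number WT samples 1 to 5 and KO samples 6 to 10, and these numbers name the replicates here. The labels do not say whether each sample came from a different mouse, so p-values measure only the spread between these samples.

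The authors deposited 1 log2 signal per probe set and array. RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of a set, and the Partek software are named in the submitters' processing notes, and their versions are not given in the sources used here. The log base was not stated either and was taken as 2 from the range of the values. Because the arrays were equalised, a shift of all genes in the same direction could not be seen, and differences of dim probe sets are compressed towards 0. No detection call came with the values, so the dimmest signals were kept and are open to background.

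The table held 23747 probe sets. The platform annotation paired 23111 of them with exactly 1 gene symbol and 0 with several, and 636 were not listed and are unnamed here. Each named gene had 1 probe set, so 23111 genes were tested. The annotation used here names no probe set for the targeted gene. An unnamed probe set carries the gene number of Ucp2 in its ID, and its values are given below with the unnamed probe sets. Places along the genome were used only as the order of genes in the RefSeq table of assembly GRCm38.p6, in which 23075 of the tested genes were found by gene number. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed.

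Values were used as deposited. KO was compared with WT by the lmFit and eBayes functions of limma 3.58.1 in R 4.3.3, with no covariate and Benjamini-Hochberg adjustment over all genes tested, and a gene was called changed at adjusted p under 0.05. A second count took genes at unadjusted p under 0.05 that differed by at least 1.5-fold. Differences are KO minus WT on the log2 scale with the standard error (SE) of the fit, and group means carry the standard deviation (SD) over 5 arrays. The number of arrays limits the precision. Simulated data were made 10 times on the 23111 genes, with 200 genes changed each time, 50 at each fold size. Noise was drawn independently for each gene. The limma test recovered 22% of genes changed by 1.25-fold, 66% at 1.5-fold, 91.2% at 2-fold and 97% at 4-fold, with 6.9 false calls per simulation on average. The adjusted threshold is stricter where fewer genes change, and measured genes vary together, so these shares may be too high for these data.

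Before the data were examined, 41 gene lists were fixed: pathways of metabolism, redox defence, growth and inflammation, markers of the cell types that a dissected colon tumour can hold, genes next to Ucp2 on its chromosome, and genes that report on sampling. Of these, 40 had at least 5 measured members and were tested with camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. The correlation estimated from the data and the fry test were run beside it. The score of a list in an array is the mean over its measured members of the log2 signal minus that gene's mean over the 10 arrays. Scores and the first 2 principal components of all genes were compared by exact two-sided permutation tests over all 252 assignments, which cannot give a p below 0.00793651.

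Genes are named by a rule fixed in advance: genes past the adjusted threshold first, and, where fewer than 12 passed in a direction, the genes with the smallest p among those at unadjusted p under 0.05 and 1.5-fold, up to 12 a direction. Predicted genes, microRNA and receptor families with numbered members, and immunoglobulin and T-cell receptor segments were counted but not named. Of each list described, up to 4 members with the smallest p are named. Other genes are said to have been chosen after their values were seen.

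The alternatives left out each array, left out dim genes, centred, quantile normalized or cyclic loess normalized the arrays again, took all probe sets, used an intensity trend with robust estimation or array weights, added the epithelium or smooth muscle score as a covariate, and moved the thresholds. A few more were added after the data were seen. Correlations between arrays ranged from 0.964 to 0.993 and 0 pairs held identical values, so every array was counted as a sample. The labels name no batch.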

Results

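The data are 10 array profiles of AOM/DSS colon tumours, 5 from WT mice and 5 from Ucp2-/- mice. They address how the knockout of this mitochondrial carrier goes with gene expression in tumours that arise in an inflamed colon. The median log2 signal of an array lay between 5.84 and 5.93. Arrays of the same genotype correlated across genes with a median r of 0.985 within WT and 0.989 within KO, and arrays of different genotype with a median r of 0.986. Xist, which is transcribed from the inactive X chromosome of female cells, was at or below 4.20 in each of the 10 arrays, and the Y-linked gene Uty at or above 8.51. Means below are over 5 arrays per genotype, with the SD after the mean and the SE after a difference.

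The first comparison asked whether genotype is a main axis of variation between tumours. Tumours of both genotypes were mixed along the first principal component, which held 33.8% of the variance. Segments of immunoglobulin variable regions and the colonocyte genes Cyp2c55, Hao2 and Slc5a8, chosen after their values were seen, were among the genes with the greatest weights on it. The mean score was 9.02 ± 23.4 (SD) in WT and -9.02 ± 18.6 in KO, a difference of -18.0 that was within the spread of the tumours (exact permutation p = 0.254). It was -9.38 without WT replicate 5 and -10.6 without KO replicate 7 (exact permutation p = 0.476 and 0.524). The second component held 13.7% of the variance and did not part the genotypes either (exact permutation p = 0.508). WT replicate 5 lay farthest out on the first component, at 48.2, against a range of -33.2 to 9.23 for the other 9 arrays.

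**Figure D1:**
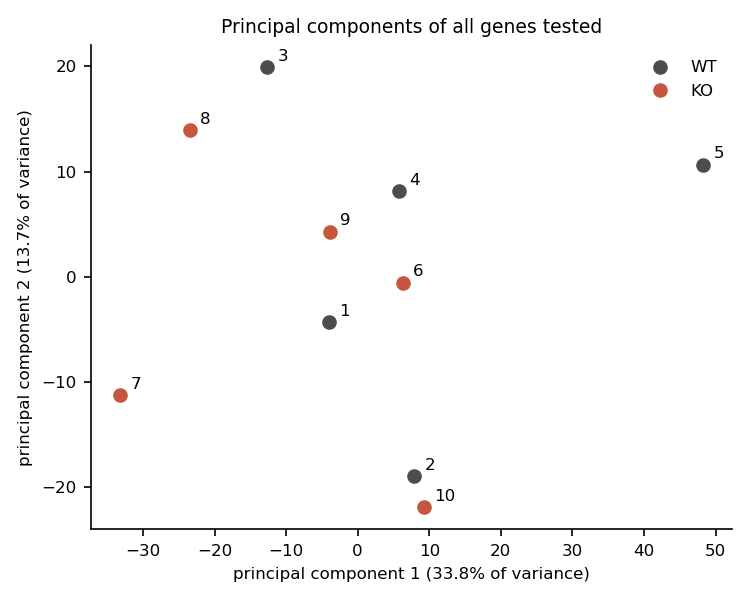
Each point is the tumour of 1 array on the first (x axis, 33.8% of the variance) and second (y axis, 13.7%) principal components, in units of log2 signal, with WT in grey, KO in red and the replicate number beside it. The genotypes overlap, and WT replicate 5 sits apart at 48.2 on the x axis.

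The second comparison set KO against WT gene by gene. The lowest p-values belonged to genes with less signal in KO tumours. Kcne3, a potassium channel subunit of the colonic epithelium, had a mean log2 signal of 10.05 ± 0.26 (SD) in WT and 9.03 ± 0.14 in KO, a 2.04-fold lower level, and Trim12a, of a family of antiviral ubiquitin ligases, had 7.52 ± 0.42 in WT and 4.39 ± 0.90 in KO. In both genes each KO tumour lay below each WT tumour. Both missed the threshold (limma adjusted p = 0.0653).

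By limma, 0 of the 23111 genes were called changed at adjusted p under 0.05, against 1103 at unadjusted p under 0.05 (514 higher and 589 lower in KO), where 1156 would come by chance. The alternatives called 0 to 3 genes, as listed below. In 193 genes the values of the genotypes did not overlap, where chance gives 0.794% of genes, or 183. At unadjusted p under 0.05 and at least 1.5-fold, 107 genes stood apart, 85 higher and 22 lower in KO. Of the 85, 42 were segments of immunoglobulin variable regions. This count moved to 174 without WT replicate 3, 66 without WT replicate 5 and 63 without KO replicate 7.

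None of the other named genes passed the adjusted threshold (adjusted p of 0.255 or more), so their values are given as measured. Among those with more signal in KO were C1qb, a chain of the complement component C1q, with a difference of 0.60 ± 0.14 (SE), Il7r, the interleukin-7 receptor chain of lymphocytes (0.84 ± 0.22), Trac, the constant part of the T-cell receptor alpha chain (0.70 ± 0.22), and Ly96, the co-receptor of the endotoxin receptor Tlr4 (0.68 ± 0.21). The interferon-induced genes Usp18, Oas2 and Rtp4 had differences of 0.82 ± 0.23, 1.16 ± 0.39 and 0.65 ± 0.22. The rest of the 12 were Guca2b, which encodes the intestinal hormone uroguanylin (0.70 ± 0.21), Tcf21, a transcription factor of mesenchymal cells (0.62 ± 0.19), Fxyd1, a regulator of the sodium pump (0.61 ± 0.20), the acute-phase protease inhibitor Serpina3n (0.95 ± 0.32) and Car9, a hypoxia-induced carbonic anhydrase (0.63 ± 0.21).

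Among the named genes with less signal in KO were the collagenase gene Mmp13 (-1.14 ± 0.24), the cytokine gene Il11 (-0.98 ± 0.26), Fosb, a component of the transcription factor AP-1 (-0.66 ± 0.22), and the noncoding RNA Wincr1 (means 4.01 in WT and 3.38 in KO). The other 8 all lie on chromosome 7. Of these, Kcne3, Lipt2 and Pgm2l1 are within 8 measured genes of Ucp2, and the named Trim genes are 143 to 151 genes away. Apart from Kcne3 and Trim12a the 8 were Lipt2, an enzyme of mitochondrial lipoate synthesis (-0.68 ± 0.15), Pgm2l1, an enzyme of sugar phosphate metabolism (-0.84 ± 0.27), and the Trim12a relatives Trim34a (-1.23 ± 0.19), Trim30d (means 6.07 in WT and 4.19 in KO), Trim5 (4.50 and 3.49) and Trim30b (4.12 and 3.43). Probes of this family can bind transcripts of its other members, so the values of single Trim genes are uncertain. The KO means of Trim12a, Trim5, Trim30d, Trim30b and Wincr1 lay under 5.14, the 95th percentile of the mean signals of 1088 olfactory receptor genes, a guide to background chosen after the values were seen. The WT means of Trim5, Trim30b and Wincr1 lay under it too. No detection call was made, and the size of the difference is not given for these 5 genes.

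**Figure D2:**
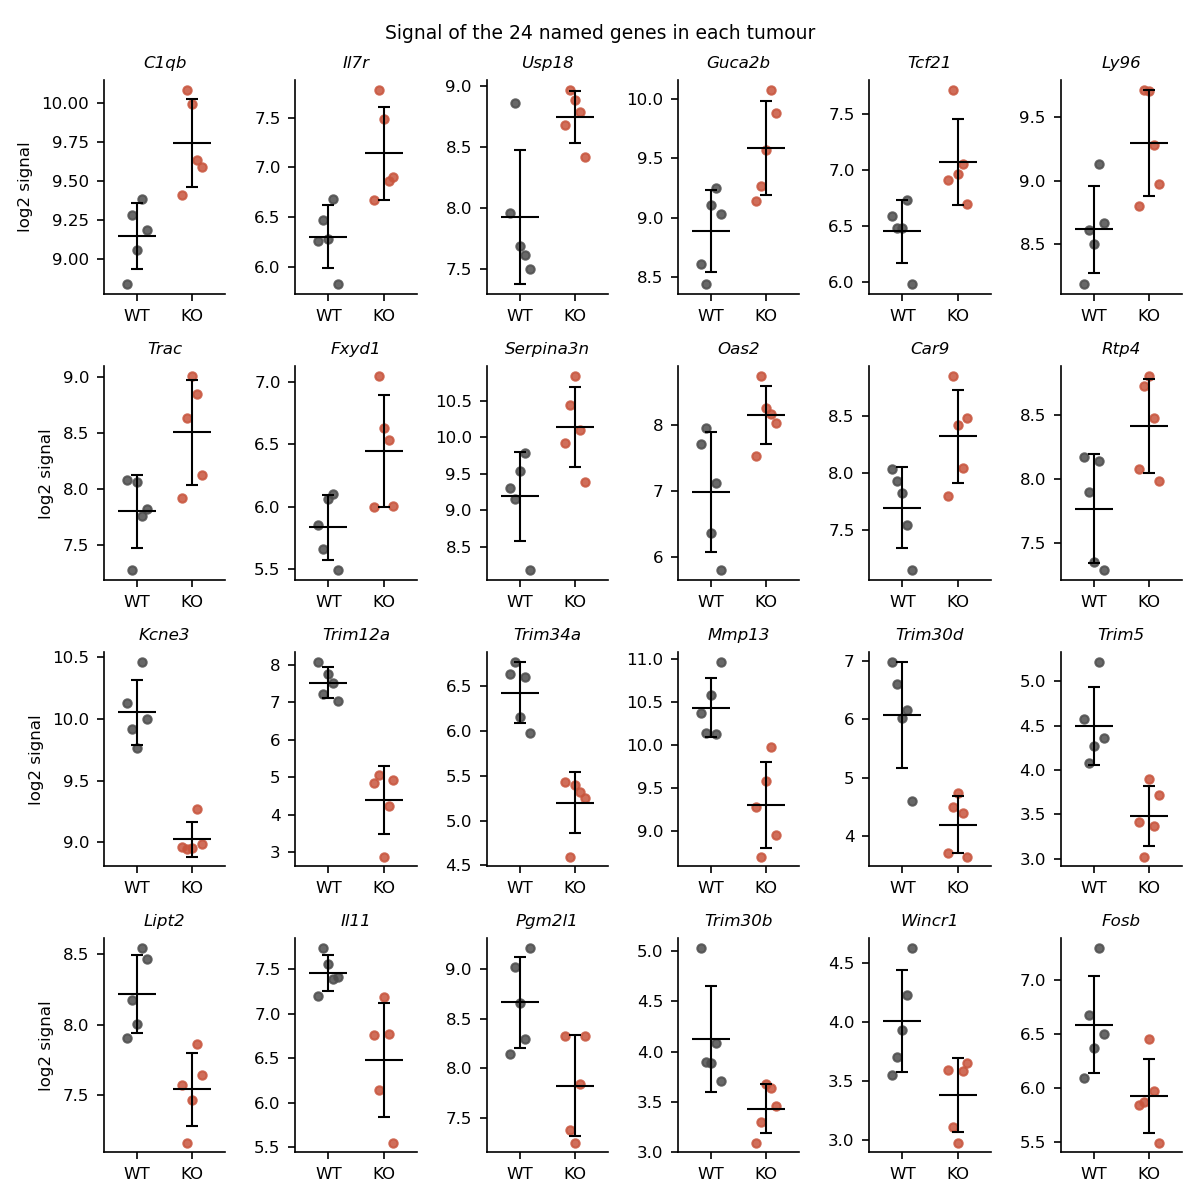
Each panel shows 1 of the 24 named genes, with log2 signal on the y axis (the range differs between panels), WT tumours in grey and KO tumours in red, and the black line and bar giving the mean and SD of 5 arrays. The WT and KO points of Kcne3 (means 10.05 and 9.03) and Trim12a (7.52 and 4.39) do not overlap.

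Genes on either side of the targeted locus made up a large part of the smallest p-values. Of 20 genes at unadjusted p under 0.001, where 23 would come by chance, 10 lay on chromosome 7, and 8 of these were among the 300 measured genes nearest to Ucp2, 150 on each side. Kcne3 and Pold3, a DNA polymerase subunit (-0.51 ± 0.10), had less signal in KO, and P2ry2 and P2ry6, receptors for extracellular nucleotides, had more (0.50 ± 0.10 and 0.37 ± 0.08). The remaining 4 were Trim34a, Trim5, Trim12a and a predicted gene beside them, 143 to 146 genes from Ucp2 and so close to the edge of the window. Among 338 other windows of 300 measured genes along the genome, the highest count was 3. These windows overlap one another, and windows sharing genes with that of Ucp2 were left out.

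The list of Ucp2 neighbours fixed in advance had 34 measured members, of which 7 were at unadjusted p under 0.05, 4 higher and 3 lower in KO. Kcne3 is not a member of this list, so the tests of the list do not cover it. Adjusted over the list alone, Pold3 and Lipt2 fell and P2ry2 and P2ry6 rose (limma adjusted p of 0.00524 to 0.00858), and 0 members passed over all genes tested. Camera, which looks for a shift in 1 direction, did not call the list (adjusted p = 0.742), and the mixed test of fry, which takes changes in either direction, did (adjusted p = 0.00595).

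**Figure D3:**
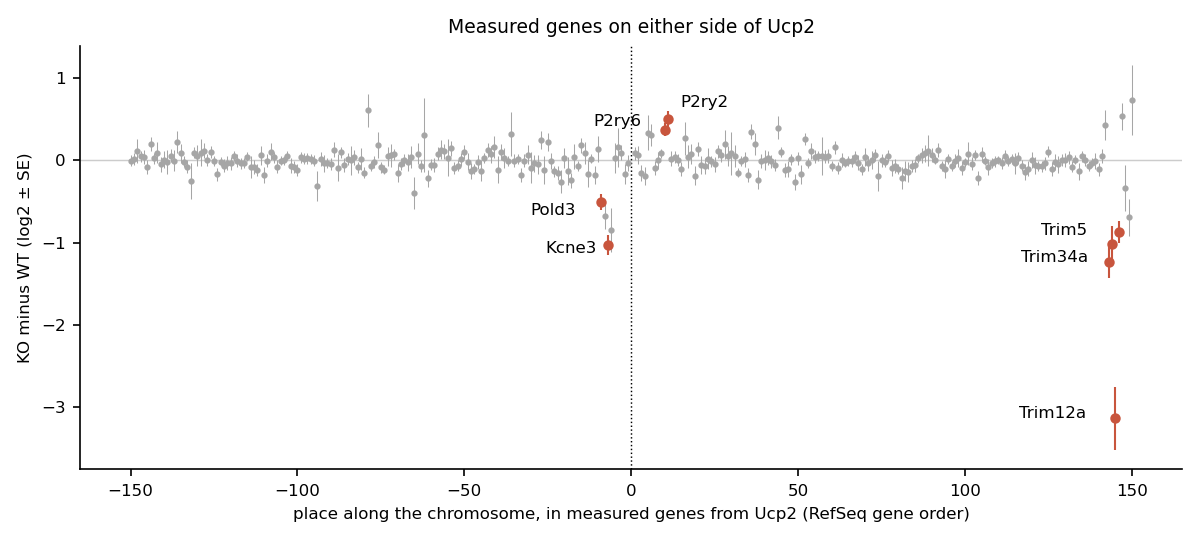
Points are the 300 measured genes nearest to Ucp2 (dotted line) in RefSeq gene order, placed on the x axis by their distance from it in measured genes, with KO minus WT log2 signal and its SE on the y axis and genes at unadjusted p under 0.001 in red. The 8 red points sit within 11 genes of Ucp2 (Pold3, Kcne3, P2ry6, P2ry2) and in the Trim cluster 143 to 146 genes away, where the unlabelled point is a predicted gene and Trim12a is lowest, with a KO mean (4.39) under the guide to background.

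Part of the macrophage genes had more signal in KO tumours. Of 20 measured markers of macrophages and dendritic cells, 10 rose when adjusted over the list alone, 0 fell, and 0 passed over all genes tested. C1qc and C1qb, chains of complement C1q, rose by 0.46 ± 0.10 (SE) and 0.60 ± 0.14, the integrin gene Itgax (CD11c) by 0.37 ± 0.09 and the membrane protein gene Ms4a7 by 0.56 ± 0.13 (limma adjusted p over the list alone = 0.00876). The other 6, named after their values were seen, were Cd68, Csf1r, Fcgr3, Mrc1, Adgre1 and C1qa, with differences between 0.31 and 0.55, while the monocyte genes Ccr2 and Cd14 (0.20 ± 0.19 and 0.11 ± 0.18) did not pass.

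The macrophage score was higher in each KO tumour (lowest -0.0593) than in any WT tumour (highest -0.0873), with a mean difference of 0.28 ± 0.07 (SE) and an exact permutation p of 0.00794, the smallest that the design allows, or 0.317 after adjustment over 40 lists. Camera called the list (adjusted p = 6.86e-16), a call lost with an estimated correlation (adjusted p = 0.126). The mixed test of fry called it (adjusted p = 0.0154) and the directional test did not (adjusted p = 0.148).

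Interferon-induced genes passed neither over all genes nor over their list alone. All 22 measured genes of the type I interferon list had positive differences, 14 of them at unadjusted p under 0.05 (5 without WT replicate 5), and 0 passed when adjusted over the list alone. Usp18, Oas2, Rtp4 and Irf9, a transcription factor of the interferon response (0.31 ± 0.10), had the smallest p. The list score differed by 0.52 ± 0.22 (exact permutation p = 0.0556). WT replicates 5 and 3 had the lowest scores (-0.817 and -0.564), and the difference was 0.38 without WT replicate 5. Camera called the list (adjusted p = 8.4e-18), with adjusted p = 0.376 with an estimated correlation.

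Of 21 markers of T and NK cells, 16 had positive and 5 negative differences, 5 were higher in KO at unadjusted p under 0.05 and 0 passed over the list alone. Beside Il7r and Trac, these were led by Foxp3, the transcription factor of regulatory T cells (0.48 ± 0.15), and Cd3g, a chain of the T-cell receptor complex (0.71 ± 0.26). The list was called by camera (adjusted p = 6.17e-06), with adjusted p = 0.454 with an estimated correlation. Its score differed by 0.27 ± 0.14 (exact permutation p = 0.0794). In 22 of 23 genes of antigen presentation by MHC class II and of the interferon gamma response the difference was positive, led by H2-Ab1 (0.40 ± 0.26) and H2-Aa (0.44 ± 0.28), with a camera adjusted p of 6.39e-05 and 0.634 with an estimated correlation. The score of this list differed by 0.33 ± 0.37, within the spread between tumours (exact permutation p = 0.389). WT replicate 5 had the lowest score of this list too (-0.925), and the mean difference of 0.33 was 0.14 without it, 0.19 without WT replicate 2, 0.16 without KO replicate 8 and 0.56 without WT replicate 1.

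Mast cell markers were positive in 10 of 12, led by the protease genes Mcpt4 (means 3.68 in WT and 4.47 in KO, both under the guide to background of 5.14) and Cpa3 (1.04 ± 0.49), and 0 passed over the list alone. Camera called the list (adjusted p = 0.000212), with adjusted p = 0.454 with an estimated correlation. The mast cell score differed by 0.42 ± 0.26 (exact permutation p = 0.135). Neutrophil markers (8 of 17 positive, among them Csf3r at 0.47 ± 0.20) and B and plasma cell markers (12 of 16 positive) were not called (adjusted p = 0.582 and 0.0862). The latter were called without WT replicate 3, KO replicate 6 or KO replicate 10 (adjusted p of 2.37e-08 to 0.0365).

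Part of the inflammatory mediators had less signal in KO tumours. Of 28 measured cytokines, chemokines and inflammatory enzymes, 4 fell when adjusted over the list alone and 0 rose. Mmp13 and Mmp10, which encode proteases that cut extracellular matrix, fell by 1.14 ± 0.24 (SE) and 0.51 ± 0.13, Il11 by 0.98 ± 0.26, and the neutrophil-attracting chemokine gene Cxcl1 by 0.47 ± 0.14 (limma adjusted p over the list alone of 0.0169 to 0.035). Ptgs2, which encodes the prostaglandin-forming enzyme COX-2, and the chemokine gene Cxcl2, both chosen after their values were seen, had differences of -1.12 ± 0.38 and -0.72 ± 0.25 and did not pass. Tnf (-0.23 ± 0.17) and Il1b (-0.37 ± 0.26), also chosen so, had differences nearer to their SE.

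The inflammatory score differed by -0.27 ± 0.12 (exact permutation p = 0.0635), with KO replicate 8 (0.232) among the WT values. Camera called the list as lower in KO (adjusted p = 0.000212), with adjusted p = 0.454 with an estimated correlation. The count of 4 members was 0 without WT replicate 3 and 1 without WT replicate 2, WT replicate 4 or KO replicate 7.

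**Figure D4:**
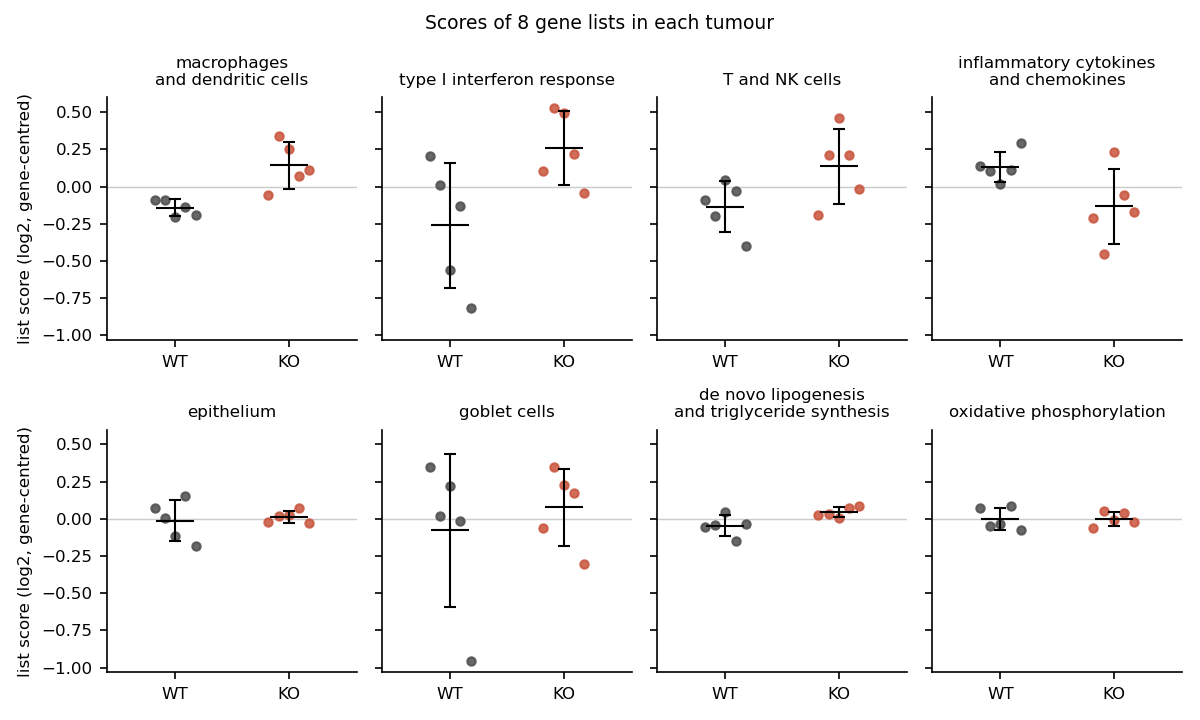
Each panel shows the score of 1 gene list (y axis, mean log2 signal of its members, each centred on its mean over the 10 arrays) in 5 WT (grey) and 5 KO (red) tumours, with the black line and bar giving mean and SD. The macrophage scores do not overlap between genotypes (0.28 apart on average), WT replicate 5 is lowest in the goblet cell panel (-0.959), and epithelium and oxidative phosphorylation scores lie together.

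A further question set by a mitochondrial carrier knockout is whether genes of energy and redox metabolism differ. Oxidative phosphorylation genes were split evenly (18 of 38 positive, mean difference 0.0014), as were genes of the tricarboxylic acid cycle (11 of 21 positive, mean 0.0035). With single arrays left out both means took either sign (-0.0178 to 0.0228 and -0.0165 to 0.0254). The respiratory chain subunit gene Ndufa8 (0.27 ± 0.09) and the ATP synthase subunit gene Atp5d (0.30 ± 0.11) had the smallest p in the first list. Neither passed over the list alone. Camera called neither list (adjusted p = 0.582 and 0.578), nor those of fatty acid oxidation and ketogenesis (14 of 21 positive, led by the carnitine carrier gene Slc25a20 at 0.29 ± 0.13; adjusted p = 0.0558), NADPH production (10 of 21 positive, led by Pgd of the pentose phosphate pathway at 0.18 ± 0.07; adjusted p = 0.469) and mitochondrial carriers (10 of 19 positive; adjusted p = 0.395). The fatty acid oxidation list was called without WT replicate 4, KO replicate 9 or KO replicate 10 (adjusted p of 0.00233 to 0.0434).

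Genes of lipid synthesis showed small positive differences. Of 24 genes of de novo lipogenesis and triglyceride synthesis 18 were positive, with a mean of 0.09 ± 0.03 (SE; exact permutation p = 0.0317, or 0.508 after adjustment over 40 lists). The acyltransferase gene Agpat2 (0.23 ± 0.09) and the desaturase genes Fads2 (0.17 ± 0.07) and Scd1 (0.36 ± 0.15) had the smallest p, and 0 members passed over the list alone. Camera called this list (adjusted p = 0.00123) and that of cholesterol synthesis (adjusted p = 0.00127), where 15 of 19 genes were positive, led by Nsdhl (0.26 ± 0.08) and Fdps (0.21 ± 0.07). With an estimated correlation the adjusted p were 0.126 and 0.454.

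Positive shifts called by camera also covered 12 of 15 genes of glutamine, glutamate and aspartate metabolism, 21 of 30 antioxidant genes and 12 of 17 glycolysis genes (adjusted p = 0.00613, 0.00945 and 0.018), with mean differences of 0.11, 0.05 and 0.09. The antioxidant mean was 0.0306 without WT replicate 3, 0.0827 without WT replicate 5 and 0.0754 without KO replicate 6, and the glycolysis mean 0.0533 without WT replicate 4 and 0.0563 without KO replicate 8. With an estimated correlation these adjusted p were 0.454, 0.454 and 0.578. Pgk1, an enzyme of glycolysis and a hypoxia target (0.45 ± 0.14), Gpx3, a secreted glutathione peroxidase (0.34 ± 0.13), and the aspartate-glutamate carrier gene Slc25a12 (0.29 ± 0.17) led these lists, and 0 members passed over any of them alone. The calls ended without WT replicate 1 for glutamine metabolism (adjusted p = 0.0854), without WT replicate 3 for antioxidant genes (0.128), and without WT replicate 4, WT replicate 5, KO replicate 8 or KO replicate 10 for glycolysis (0.0584 to 0.15).

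Hypoxia targets (13 of 18 positive, with Car9 and Pgk1 first) and genes of the unfolded protein response (18 of 22 positive, led by Herpud1 at 0.36 ± 0.19) were called as higher in KO (adjusted p = 0.0237 and 0.00459), with adjusted p = 0.578 and 0.634 with an estimated correlation. Both calls ended without WT replicate 4 or KO replicate 10, that of hypoxia targets also without WT replicate 3 or KO replicate 7, and that of the unfolded protein response without WT replicate 5 (adjusted p of 0.056 to 0.226).

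Markers of proliferation had small negative differences. Of 29 cell cycle genes 27 were negative, with a mean of -0.12 ± 0.10 (SE), or -0.0569 without WT replicate 5, and Top2a, the topoisomerase of dividing cells (-0.30 ± 0.12), and the mitotic kinase gene Bub1 (-0.29 ± 0.13) had the smallest p. Camera called the list (adjusted p = 0.00148), with adjusted p = 0.657 with an estimated correlation, and the call ended without WT replicate 1 (adjusted p = 0.0587) or WT replicate 5 (adjusted p = 0.184). Wnt and beta-catenin targets (14 of 23 negative, led by Cd44 at -0.19 ± 0.14), p53 targets (12 of 17 negative, led by Plk2 at -0.43 ± 0.18) and extracellular matrix genes (14 of 25 negative, with Col4a2 at -0.20 ± 0.06 and Col1a1 at -0.25 ± 0.10) were not called (adjusted p = 0.742, 0.742 and 0.94).

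Epithelial markers differed by less than the spread between tumours (mean difference 0.03 ± 0.06 over 14 genes; exact permutation p = 0.683). The mean was -0.0173 without WT replicate 5, and camera called the list as higher without WT replicate 1 or WT replicate 4 (adjusted p = 0.0435 and 0.00827) but not with all arrays (0.144). Goblet cell genes (14 of 15 positive, led by Spink4 at 0.23 ± 0.10) and absorptive colonocyte genes (14 of 20 positive, led by Guca2b) were called as higher in KO (camera adjusted p = 0.00424 and 0.0237), with adjusted p = 0.634 and 0.641 with an estimated correlation. The goblet cell and colonocyte scores differed by 0.15 ± 0.26 and 0.14 ± 0.29, within the spread between tumours (exact permutation p = 0.667 and 0.754). WT replicate 5 had a score of -0.959 for goblet cells and -1.10 for absorptive colonocytes, and without it both mean differences turned negative (-0.07 and -0.11). The colonocyte call also ended without KO replicate 7 (adjusted p = 0.231) or KO replicate 8 (0.0773). Tuft cell genes (6 of 11 negative, led by Pou2f3 with means of 3.98 in WT and 3.79 in KO, both under the guide to background), enteroendocrine genes (11 of 17 negative) and Paneth-like cell genes (8 of 12 positive, with Mptx2 at -1.38 ± 0.52) were not called (adjusted p = 0.582, 0.849 and 0.534), the last except without KO replicate 8 (0.0289).

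Stromal markers were mostly positive. Smooth muscle genes (15 of 17, led by Acta2 at 0.42 ± 0.20) and fibroblast genes (18 of 20, led by Fbln1 at 0.45 ± 0.17) were called as higher in KO (camera adjusted p = 0.000369 and 0.00106), with adjusted p = 0.578 for both with an estimated correlation. Their scores differed by 0.26 ± 0.20 and 0.14 ± 0.10 (SE), within the spread between tumours (exact permutation p = 0.246 and 0.222). Endothelial (10 of 18 positive), enteric nervous system (10 of 16 positive) and adipocyte genes (8 of 14 positive) were not called (adjusted p = 0.335, 0.582 and 0.742), the first except without WT replicate 4 or KO replicate 10 (0.0445 and 0.00793). Markers of squamous epithelium of the anal canal and of pancreas, small intestine and stomach, which would show neighbouring tissue in a sample, were not called either (adjusted p = 0.94 and 0.144), the second except as lower without WT replicate 5 (0.0179).

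Among genes that report on sampling, immediate early and heat shock genes were called as lower in KO (camera adjusted p = 0.0237, with adjusted p = 0.634 with an estimated correlation), with 13 of 21 negative, led by Atf3 (-0.30 ± 0.09) and Fosb. Without WT replicate 2 their mean difference of -0.07 became 0.05, and the call also ended without WT replicate 4, KO replicate 6 or KO replicate 10 (adjusted p of 0.0894 to 0.119).

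Circadian clock genes were not called (7 of 17 positive; adjusted p = 0.643), and their mean (0.0168, or -0.0303 without WT replicate 1) and median (-0.0269) had opposite signs, as in the lists of NADPH production, oxidative phosphorylation, enteroendocrine cells and neutrophils.

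Over the 40 lists, camera called 19, of which 16 were higher and 3 lower in KO. Other splits of the 10 arrays into groups of 5, which mix the genotypes, gave 6 to 20 called lists. A camera call at the preset correlation is therefore weak evidence of a difference between genotypes. With an estimated correlation 0 were called, and the directional test of fry called 0. By exact permutation tests of the scores, 2 lists were under 0.05 before adjustment, macrophages and lipogenesis, and 0 after it.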

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

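The tests of placement along the genome, of Trim cross-hybridisation and of linked strain DNA were chosen after the results they bear on had been seen. Over 134 groups of 5 arrays checked for a sample far from the others, 5 stood out, where chance gives about 7.

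WT replicate 5 had low scores of differentiated epithelial genes. Its absorptive colonocyte score was -1.10, against 0.0331 to 0.372 in the other WT tumours, and its goblet cell score was -0.959, against -0.0135 to 0.346.

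In Kcne3, KO replicate 9 had a log2 signal of 9.27, against 8.95 to 8.99 in the other KO tumours. In Trim34a, KO replicate 7 was at 4.60, against 5.25 to 5.43. In Trim30b, WT replicate 1 was at 5.03, against 3.71 to 4.09 in the other WT tumours. Among the 636 unnamed probe sets, which took no part in the comparisons, 1 passed adjusted p under 0.05 when all probe sets were tested together by limma (adjusted p = 0.00576). It lay at 10.84 to 11.55 in WT and 9.73 to 9.97 in KO, so KO signal was lower in each array and still far over the guide to background of 5.14. It carries no gene name in the annotation used here, but it is the probe set whose ID carries the gene number of the targeted gene, Ucp2. Its mean was 11.30 in WT and 9.84 in KO.

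The window around Ucp2 on chromosome 7 held 8 of the 20 smallest p-values. Pold3, Kcne3, Trim34a, Trim5, Trim12a and a predicted gene were lower and P2ry2 and P2ry6 higher in KO. Other Trim genes of the window went both ways, among them Trim12c (0.54 ± 0.16, SE) and Trim30b (means 4.12 in WT and 3.43 in KO). Chance placement is argued against, since 0% of 338 other windows of 300 measured genes held as many genes at p under 0.001 and the highest held 3. These windows overlap, so shares of them count some stretches of the genome more than once. Windows sharing genes with that of Ucp2 were left out. Cross-hybridisation between Trim genes as the whole cause is argued against too, since 4 of the 8 were neither Trim genes nor beside one and other windows held at most 3 such genes. A predicted gene inside the Trim cluster is left out of the 4, and the margin of 1 gene is narrow. DNA of another strain carried along with the knockout allele is a candidate explanation as a hypothesis, because the window's expressed genes had a median absolute t of 1.13, above that of 98.2% of other windows (highest 1.26), and moved both ways. Whether such DNA would alter transcript levels or only the binding of probes, and whether the targeting itself acts on neighbouring genes, stays open and was not tested. The labels give C57BL6/J for both genotypes and no breeding history.

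Among 100 of the 126 splits of the 10 arrays into groups of 5, the real one included, 7 gave as many members of the neighbour list fixed in advance at unadjusted p under 0.05 (7 in the real split, highest other 11), so chance cannot be excluded for that count.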

How the results depend on the processing

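Settings that left out immunoglobulin and T-cell receptor segments or genes near Ucp2, or took the macrophage score as a covariate, and the counts of list members, were chosen after seeing the data. The number of changed genes (0) was 2 with dim genes left out. It was 3 with all probe sets (Kcne3, Trim12a and the unnamed probe set that carries the gene number of Ucp2). It was 1 with an intensity trend and robust estimation, 1 with the epithelium score as a covariate and 2 at adjusted p under 0.1. With single arrays left out it was 0 to 2 (2 without WT replicate 3, 1 without KO replicate 8). Kcne3 passed adjusted p under 0.05 in 4 of 19 alternatives and Trim12a in 2. Their adjusted p ranged from 0.00727 (Trim12a without KO replicate 8) to 0.9998. The latter came for both genes with the macrophage score, which itself parts the genotypes, as a covariate. The 107 genes at unadjusted p under 0.05 and 1.5-fold became 68 with the smooth muscle score as a covariate, 49 at 2-fold, 67 without immunoglobulin and T-cell receptor segments, and 63 to 174 with single arrays left out (174 without WT replicate 3, 66 without WT replicate 5, 63 without KO replicate 7). The 19 called lists became 0 with an estimated correlation, 0 by fry, 6 with the macrophage score as a covariate, and 15 to 20 with single arrays left out. Of the 19, 10 stayed called without each array in turn and 9 did not. The 4 inflammatory members became 0 with the macrophage score as a covariate and 0 to 6 with single arrays left out. Counts of macrophage members (9 to 12) and of Ucp2 neighbours (5 to 8), the 0 list scores past adjustment, and the first principal component (-18.0, but -9.38 without WT replicate 5 and -10.6 without KO replicate 7) kept their side of the threshold, or stayed within 1.5-fold, in the alternatives run on them.

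Some differences turned direction. With the smooth muscle score as a covariate the absorptive colonocyte and goblet cell means were -0.131 and -0.0618. With single arrays left out they ranged from -0.113 to 0.254 and from -0.0672 to 0.259, and immediate early genes from -0.118 to 0.0531. With the macrophage score as a covariate, Oas2 was at -0.00145, Car9 at -0.112 and Rtp4 at -0.0290, and the list means were -0.00736 for glycolysis, 0.0438 for cell cycle, -0.0205 for type I interferon, -0.0559 for hypoxia, -0.0578 for the unfolded protein response, -0.291 for absorptive colonocytes, -0.248 for goblet cells, -0.0344 for T and NK cells, -0.0917 for fibroblasts and -0.0499 for smooth muscle. That score parts the genotypes, so this setting takes much of the genotype difference with it by construction, and the cause of the other changes was not tested. The list behind a covariate has no value under it. Of the other results on single lists and genes, 716 list values stayed on their side of the threshold, 83 lost it, 19 gained it and 15 turned direction. Of the gene values, 442 stayed, 6 gained it and 3 turned direction. Averaging the probe sets of a gene changes nothing here, as each gene had 1, and was not run. No paired analysis was possible because the genotypes share no replicate number.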

Other observations

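The tests on macrophage markers, the tests of WT replicate 5 and of plasma cell genes, and the choice of antibody segments as a group came after their values had been seen. The counts of genes and lists over other splits of the arrays were planned.

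Segments of the variable regions of antibodies, which are joined in B cells and transcribed at high levels in plasma cells, had more signal in KO tumours in 189 of 206 measured segments. Of the 206, 46 were higher and 1 lower at unadjusted p under 0.05, with a median difference of 0.85, and 27 were higher without WT replicate 5. The mean score over the segments differed by 0.86 ± 0.44 (SE) between genotypes (exact permutation p = 0.0714), from -1.69 in WT replicate 5 to 1.20 in KO replicate 7. Segments share sequence, so their probes cannot be taken as independent. The score of 4 plasma cell genes that are no antibody chains (Jchain, Mzb1, Tnfrsf17 and Derl3) differed by 0.41 (exact permutation p = 0.302), and by 0.15 without WT replicate 5 (exact permutation p = 0.587). Jchain, which joins antibody units, differed by 0.69 ± 0.46 over all arrays.

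WT replicate 5 alone cannot be told apart from a difference between genotypes: without it the median difference was 0.51 and that of the score 0.55, with an exact permutation p of 0.159, and 9 arrays leave this open. Plasma cell content may set the segment signal of a tumour: after centring each genotype, the segment score followed the plasma cell score over the 10 arrays with Spearman rho = 0.927 (permutation p = 0.00034) and Pearson r = 0.978 (permutation p = 3e-05), and r was 0.938 without the 2 arrays farthest from the median. The relation was also tested with a score of 6 plasma cell genes (Spearman rho = 0.903, permutation p = 0.00083), and these p-values were not adjusted. Of 100 splits of the arrays, 8 gave a difference in segment score as large as the real 0.865 (highest other 1.11), so chance cannot be excluded for the difference between genotypes.

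Macrophage markers were higher in KO, by 0.28 in the mean score. The tables argue against WT replicate 5 alone as the cause: the difference was 0.27 without it, and its score (-0.191) was above that of WT replicate 3 (-0.205). The exact permutation p without WT replicate 5 was 0.0159. As the scores of the genotypes did not overlap, a low p there was nearly fixed in advance and adds little. They also argue against the part of the epithelial share that the epithelium score follows as the whole cause: that score differed by 0.03 ± 0.06 (SE), or by -0.0173 without WT replicate 5. With the epithelium score as a covariate the macrophage difference was 0.276 ± 0.077 and 10 markers still passed over the list alone. A score that differs so little between genotypes could hardly move the macrophage difference, so this fit adds little. A lower epithelial share of the KO tumours beyond what that score follows cannot be told apart from a change in macrophages, because abundant epithelial transcripts would hide a small loss: scores of endothelium, fibroblasts, neutrophils and smooth muscle were higher by 0.12 on average, and the excess of the macrophage score over them, 0.17, had an exact permutation p of 0.0873. None of the 20 measured macrophage markers is in another list. Chance cannot be excluded. Of 100 splits, 1, the real one, gave a macrophage difference as large as 0.285 (highest other 0.273), but this score was singled out from 40, its exact permutation p adjusted over them was 0.317, and in 18 of 100 splits some list score was as many standard errors apart as this one (3.84, highest other 6.56). The genotype stays open as an untested explanation.

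For the counts of genes at unadjusted p and of called lists, chance cannot be excluded. Of 100 splits, 28 gave at least its 107 genes at unadjusted p under 0.05 and 1.5-fold (highest other 421), and 8 gave at least its 19 called lists (highest other 20, lowest 6). With 0 changed genes in the real split all 100 splits gave at least as many by construction (highest other 1), so that count tests nothing. The split with 421 genes set WT replicates 1 and 3 and KO replicates 7, 8 and 9 against the rest and had 173 genes at p under 0.001, where 23 would come by chance. This split was picked as the highest of 100. Its first group holds the 5 arrays with negative scores on the first principal component, on which antibody segments and colonocyte genes weigh. A split along the component of greatest variance tends to give a high count, so the count alone does not show separate groups of samples. What lies behind the component was not tested.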
